A study of Mus musculus with 6 samples.

How the data were processed

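Total RNA was extracted with ISOGEN2 from the region on both sides of the urethra in embryonic mouse external genitalia, and a sequencing company prepared the libraries, per the labels' protocols. The 6 libraries were taken from wild-type ICR males and females at E13.5 and E16.5, and from C57BL/6 males at E16.5 labelled MafB GFP/+ or MafB GFP/GFP (KO), 1 library per group. The files came as 3 tables of 2 libraries each, with 22837 genes per table, and the tables were normalized separately.

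The values are FPKM per gene and library, as deposited by the authors, per the sheet names, which carry the name of the gene-level tracking table of Cufflinks and Cuffdiff. The aligner, the software versions, the annotation and the genome build are not given in the sources used here. The tables hold no counts, intervals or status flags. Symbols of 27 genes had become dates in a spreadsheet and were not restored. No mitochondrially encoded gene is in the tables. Of all genes, 3783 share a locus with another symbol, and reads from near-identical or overlapping genes cannot be separated. All gene names and positions are those of the files, with starts made 1-based.

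Each comparison used the log2 ratio of FPKM + 1 between the 2 libraries of a table, which understates the change of low genes. A gene entered when it reached FPKM 1 in at least 1 of the 2 libraries, and it passed the size rule at a log2 ratio of 1 or more, or −1 or less. With 1 library per group no test was run and no p-value is given. The stage comparison set levels from separately normalized tables side by side, after rescaling each library to a total of 1000000 over all genes, and counted genes past the rule in both sexes. Overlaps were set against the number that independent lists of the same sizes would share, and correlations across genes were computed with and without the sex chromosomes. No library is shared between the comparisons in an overlap. The stage changes of the fixed lists include the E16.5 libraries of the sex comparison they are read beside.

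In all, 25 gene lists with 413 genes were fixed before the data were examined, and 397 of the genes are in the tables. The lists cover Y-linked and X-inactivation genes as checks of the labels, the Maf family, steroid receptors and enzymes, androgen response, hedgehog, genital patterning, Wnt targets, Wnt antagonists, BMP and TGF-beta, cell cycle, extracellular matrix, smooth muscle, actomyosin, immediate-early and mitochondrially encoded genes, and marker genes of 9 cell types: skeletal muscle, cartilage and bone, basal epithelium, differentiated epidermis, urothelium, macrophage, erythroid, endothelium, and neural and glial cells. Mafb belongs to both the Maf family and the androgen response list. The list called immediate-early here was fixed as immediate-early and stress genes, and it also holds the heat shock genes Hspa1a and Hspa1b. The median log2 ratio of each list with at least 5 measured genes was placed among the medians of 10000 random lists of the same size matched in 20 bins of mean expression. A list was said to stand apart in the lowest or highest 2.5% of them, which describes these libraries and is not a test of the condition. Bootstrap bounds of a list median are the 2.5th and 97.5th percentiles over 10000 resamples of the genes in the list. They treat those genes as independent and cover no variation between embryos or dissections. A pair of further sets, of secreted liver proteins and of late cornified envelope genes, were put together after their values were seen.

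Named genes followed a rule fixed before the data were examined: Mafb and the sex-linked genes as checks of the labels; the 10 highest and 10 lowest ratios past the size rule, leaving out sex-linked list genes, unnamed predicted genes and small RNAs; for each list that stood apart or had 3 genes past the rule, the 2 genes with the largest change and the 2 with the highest FPKM; and the steroid and Maf family lists with Shh, Ptch1, Gli1, Axin2, Lef1, Mki67, Acta2 and Myh11. For the stage comparison the 10 highest and 10 lowest by the smaller of the ratios in the 2 sexes were named. Genes named as shared between comparisons, or as partners of a gene in a near-identical or overlapping family, were chosen after their values were seen.

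Depth was estimated from the spacing of low FPKM values in genes with a single transcript of at least 1500 bases, which gave 13900000 to 17400000 fragments per library, with a coherence of 0.350 to 0.741, where 1 would put every value on a whole number of fragments. Fold intervals are exact Clopper-Pearson intervals at 95% on the fragments so derived. They are approximate, cover counting error only, and are left out where the transcript length was unknown. Genes listed at 0 were given no fold. Transcript length and GC content came from transcripts in GENCODE M21 with a RefSeq mRNA accession and were found for 93.8% of genes.

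The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, with random seed 7. The scripts were tested on simulated data with 200 changed genes per comparison. These were drawn from genes with a mean FPKM of 2 or more and only raised, so changes in lower genes were not simulated. All 200 genes changed 4-fold were recovered in each comparison; of those changed 2-fold, right at the threshold, 55 were recovered in the E13.5 sex comparison, 44 in the E16.5 sex comparison and 46 in the Mafb comparison. Between 1 and 6 unchanged genes passed in each. Of 100 random lists of 25 genes, 4, 4 and 7 fell outside the range in the same order.

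The alternatives fixed beforehand were pseudocounts of 0.1 and 5, no minimum level and a minimum FPKM of 5, rescaling to 1000000, centring on the median gene, leaving out erythroid, muscle and epidermal genes before rescaling, 10 expression bins, a 1.5-fold size rule and leaving out the cell type markers. Chosen after seeing the data were a run without predicted genes, pseudogenes, small RNAs, histones and near-identical families, and a run with the trend of the ratios on GC content and length removed by lowess with a span of 0.3. Gene families of near-identical copies or overlapping units, 11 in all, were put together and widened after values were seen.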

Results

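RNA from the region on both sides of the urethra in the external genitalia of mouse embryos was sequenced in 6 libraries, 1 for each of 6 groups. In ICR mice, an outbred stock, there was 1 male and 1 female library at E13.5 and 1 of each at E16.5, where noon of the day of the vaginal plug is E0.5. In C57BL/6 males at E16.5, 1 library was labelled heterozygous and 1 homozygous for an allele that carries GFP at the Mafb gene, which encodes a large Maf transcription factor. No group had a replicate, so no difference below has a replicate check, and each compares a pair of libraries rather than a pair of conditions. The deposited FPKM values summed to between 639789 and 780922 per library. Between 12444 and 13443 genes reached FPKM 1, and the spacing of the values put the depth at about 13900000 to 17400000 fragments. Fold values are ratios of FPKM, with approximate 95% intervals that cover counting error only, and positions are 1-based on a genome build that is not given in the sources used here.

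The genes that check the labels came first. Mafb (chromosome 2, 160363677 to 160367065 in the files) stood at FPKM 2.32 in the E13.5 male, 2.47 in the E13.5 female, 106.7 in the E16.5 male, 38.9 in the E16.5 female, 84.5 in the library labelled heterozygous and 83.3 in the library labelled homozygous. As deposited, Mafb was therefore not lower in the library labelled homozygous than in that labelled heterozygous, at a ratio of 0.986 (95% interval 0.941 to 1.03). With both libraries rescaled to the same total, its log2 ratio was −0.18, where the median gene stood at −0.16. A gene-level FPKM does not separate coding from untranslated sequence: in GENCODE M21, Mafb has a single exon of 3363 bases, of which 969 are coding, and the labels do not say which part the GFP allele keeps. The value can therefore neither bear out the homozygous label nor contradict it. Sex labels matched the sex-linked genes in all 6 libraries. Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in both female libraries and at FPKM 5.14 or more in the 4 male ones, while Xist stood at 134 and 183 in the females and at 0.032 or less in the males.

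**Figure D1:**
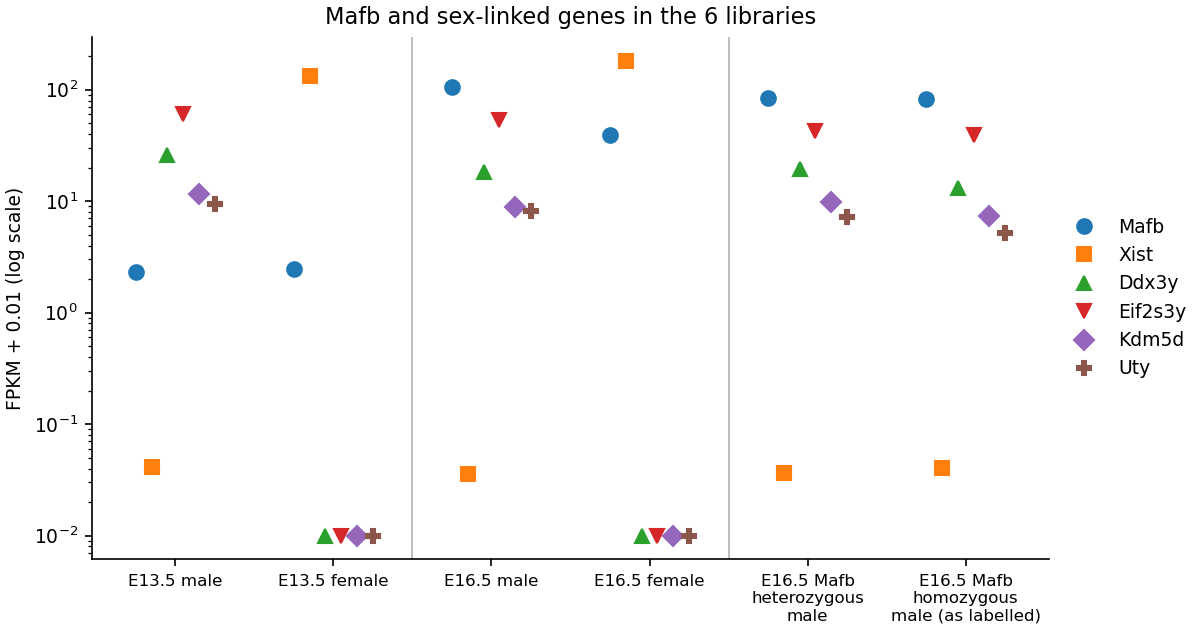
FPKM + 0.01 (log axis) of Mafb, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty in the 6 libraries, 1 point per gene and library, with grey lines between separately normalized tables. Mafb was at 84.5 in the library labelled heterozygous and 83.3 in the library labelled homozygous, and Xist was above 100 only in the 2 female libraries.

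At E13.5, skeletal muscle genes were far lower in the male library than in the female one. Extracellular matrix, basal epithelium and Wnt pathway genes were slightly higher in the male, and Mafb, Ar and Srd5a2 were close to equal. The comparison asked how far the region differs between the sexes at the earlier stage. Of 12715 genes at FPKM 1 or more in at least 1 of the libraries, 26 were at least 2-fold higher and 67 at least 2-fold lower in the male, on the scale of FPKM + 1. Counting error alone, simulated for the 12123 of these genes with a known transcript length, gave 0.9 in each direction, against 23 higher and 64 lower among them.

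Mylpf, a light chain of fast skeletal myosin, stood at FPKM 1.08 in the male and 30.5 in the female, 28.1-fold lower (14.3 to 60.8). Actc1 was 20.6-fold lower (14.3 to 30.3), Tnnc1 14.8-fold (8.16 to 30.4) and Myog 111-fold (25.3 to 770) in the male, and Sln was listed at 0 there. The skeletal muscle list had a median log2 ratio of −2.36 relative to the median gene, below all 10000 matched random lists, and 10 of its 12 measured genes were at least 2-fold lower. The neutrophil genes S100a8 and S100a9, at FPKM 21.1 and 5.84 in the female, were listed at 0 in the male. Foxl2 was 2.68-fold higher in the male (2.15 to 3.36). Amd2, Rps27, Eif3j1, Cers1 and Snurf headed the male-higher genes, but each shares a locus or near-identical sequence with another gene. Amd1, Eif3j2, Gdf1 and Snrpn, the partners of Amd2, Eif3j1, Cers1 and Snurf, were lower in the male, by 0.69 to 1.14 times the FPKM that the named gene was higher. Rps27rt was too abundant to show such a shift for Rps27.

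Several lists shifted slightly. In the male, the extracellular matrix list had a median of 0.20, with 26 of 29 genes above 0, led by Col14a1 at 1.71-fold (1.59 to 1.84) and Tnc at 1.60-fold (1.54 to 1.66). Basal epithelium genes had a median of 0.18, with Cdh1 at 1.41-fold and Dsp at 1.42-fold, and both lists lay above all matched random lists. Wnt antagonists had a median of 0.21, with Frzb 1.43-fold and Sfrp2 1.22-fold higher, and Wnt targets one of 0.15, with Znrf3 1.44-fold higher. Genital patterning genes had a median of 0.12, with 16 of 24 above 0, Hoxd11 1.35-fold and Sall1 1.25-fold higher. Cell cycle genes (0.01, 15 of 26 above 0) and actomyosin genes (0.04, 14 of 22) also stood apart, but neither did once the trend of the ratios on GC content and transcript length was removed. With libraries rescaled to the same total, 25 of the cell cycle genes and 21 of the actomyosin genes were above 0, and the actomyosin list did not stand apart. Ptch1 was 1.5-fold higher (1.44 to 1.56) while the hedgehog list as a whole did not stand apart.

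Other lists lay lower in the E13.5 male. Neural and glial genes had a median of −0.32, with Prph 3.45-fold and Stmn2 2.82-fold lower. Smooth muscle genes had a median of −0.16, with Acta2 1.59-fold and Des 1.62-fold lower, although Myh11 was 1.85-fold higher (1.63 to 2.10). That median was −0.08 with the trend removed, and the list did not stand apart with no minimum level. Endothelial genes had a median of −0.14, with Egfl7 1.33-fold lower, although Erg was 1.41-fold higher (1.28 to 1.54). Macrophage genes had a median of −0.11, with Lyz2 1.98-fold lower, and did not stand apart with a pseudocount of 5, with no minimum level or with the trend removed. Genes of the BMP and TGF-beta pathways had a median of −0.11, with Bmp5 1.53-fold lower, which did not stand apart with a pseudocount of 5 or a minimum FPKM of 5. Mafb, at 0.939 (0.726 to 1.22), Ar at 1.06 (0.890 to 1.27) and Srd5a2 at 1.03 (0.873 to 1.20) did not differ detectably at this depth. Lists of the Maf family, steroid receptors and enzymes, androgen response, hedgehog, cartilage and bone, differentiated epidermis, urothelium, erythroid and immediate-early genes did not stand apart, with medians from −0.18 to 0.05, but the erythroid list did with the trend removed (−0.21), with a pseudocount of 0.1 (−0.26) and at a minimum FPKM of 5 (−0.47), and differentiated epidermis did with no minimum level (0.26).

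At E16.5, Mafb was higher in the male than in the female library, and genes of the late, cornifying epidermis were much higher. Cell cycle genes were slightly higher in the male. Secreted liver proteins, skeletal muscle, cartilage, hedgehog and extracellular matrix genes were lower there, and so were Ar and Esr1. The comparison asked what differs between the sexes at the stage when the male urethra is closing. Of 13651 genes, 237 were at least 2-fold higher and 122 at least 2-fold lower in the male. Among the 13019 with a known length these were 228 and 120, against 4.25 and 3.40 from counting error alone. With each library rescaled to the same total the split was 191 higher and 288 lower, so the share of male-higher genes was 66.0% as deposited and 39.9% rescaled. The rescaling moved the median of all genes to −0.22 at E16.5, 0.13 at E13.5 and −0.16 in the Mafb comparison, and list medians are therefore given relative to the median gene. Counts of list genes above or below 0, and gene folds with their intervals, are as deposited. At E16.5, rescaling makes male-higher folds smaller and male-lower folds larger.

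Mafb was 2.74-fold higher in the E16.5 male as deposited (2.60 to 2.89). Rescaled to equal totals it stood at 136.6 in the male and 59.3 in the female, a smaller ratio. In the differentiated epidermis list, all 17 measured genes were higher in the male, with a median of 1.01, above all matched random lists. The list summed to FPKM 22005 in the male and 11612 in the female. In the separately normalized C57BL/6 male libraries it summed to 10317 (labelled heterozygous) and 14055 (labelled homozygous), so the former lay below the ICR female. Lor stood at FPKM 4672 against 1759, 2.66-fold higher (2.63 to 2.69), and Krtdap was 1.94-fold higher (1.88 to 2.0). Flg2 was 5.94-fold (4.77 to 7.53) and Sprr2d 2.99-fold (2.13 to 4.17) higher. The late cornified envelope genes differed more: Lce1a2 was 26.6-fold (20.5 to 35.6), Lce1h 26.0-fold (17.8 to 40.5) and Lce3b 35.1-fold (15 to 91.9) higher, and the protease gene Klk14 22.8-fold (16.7 to 31.1). Summed FPKM of the 21 late cornified envelope genes, a set put together after their values were seen, was 3715 in the male and 390.2 in the female.

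**Figure D2:**
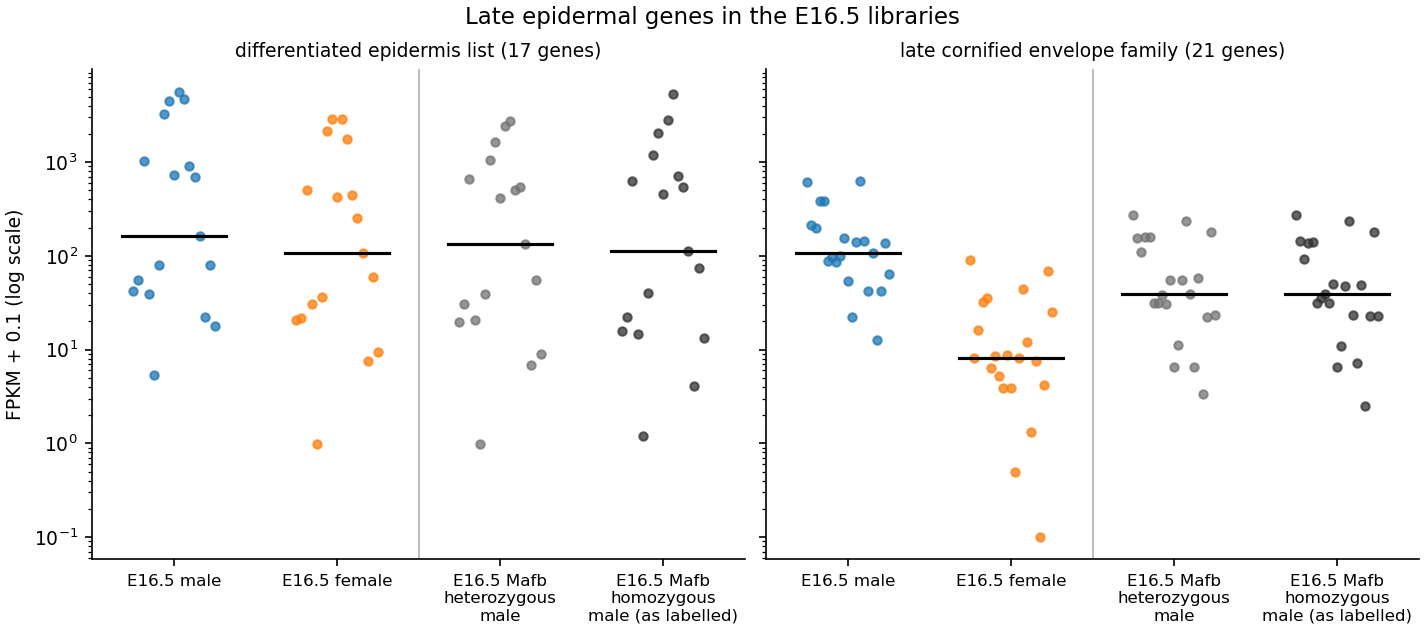
FPKM + 0.1 (log axis) of the differentiated epidermis list on the left and of the late cornified envelope genes on the right in the 4 E16.5 libraries, with 1 point per gene, black bars for medians and a grey line between separately normalized tables. The late cornified envelope genes summed to FPKM 3715 in the E16.5 male, 390.2 in the E16.5 female, 1685 in the library labelled heterozygous and 1578 in the library labelled homozygous. In the same order, the differentiated epidermis list summed to 22005, 11612, 10317 and 14055.

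As deposited, the 26 cell cycle genes were all higher in the E16.5 male, with a median of 0.29. With libraries rescaled to the same total, 16 of them were higher and 10 lower. Ube2c was 1.5-fold (1.35 to 1.63) and Birc5 1.43-fold (1.32 to 1.54) higher. Immediate-early and stress genes had a median of 0.29, with the heat shock gene Hspa1b 1.57-fold higher (1.49 to 1.65), although Jun was 1.27-fold lower. Macrophage genes had a median of 0.23, with Ms4a7 3.45-fold (1.64 to 7.56) and Lyz2 1.58-fold higher, but the median was 0.02 and inside the range of random lists once the GC content and length trend was removed.

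Lower in the E16.5 male were genes of secreted liver proteins: Alb at 23.2-fold (17.9 to 30.0), Afp at 20.8-fold (14.9 to 30.6), Apoa1 at 21.2-fold (10.5 to 45.2), Ahsg at 29.4-fold (14.1 to 86.6) and Ttr at 36.1-fold (9.16 to 291). Dpp6 was 4.54-fold, Ackr1 4.55-fold and Cadm3 3.95-fold lower. Skeletal muscle genes had a median of −1.34, with Actc1 6.05-fold (3.66 to 10.4) and Mylpf 3.27-fold (1.80 to 6.06) lower. Cartilage and bone genes had a median of −0.41, with Alpl 2.12-fold and Col9a2 1.79-fold lower, and one of −0.26 with the trend removed. In the erythroid list (median −0.50), the embryonic globin Hbb-y was 2.55-fold lower (1.94 to 3.41). The adult globins went the other way: their near-identical copies cannot be separated, and the summed alpha and beta copies were 2.37-fold and 2.45-fold higher in the male. The erythroid median did not stand apart at a minimum FPKM of 5.

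Signalling and patterning lists were lower in the E16.5 male as well. Hedgehog genes had a median of −0.33, with 12 of 14 below 0. Foxf1 was 2.03-fold (1.69 to 2.45), Ptch1 1.78-fold (1.64 to 1.93), Shh 1.22-fold (1.03 to 1.45) and Gli1 1.20-fold (1.15 to 1.25) lower. Wnt antagonists had a median of −0.16, with Dkk2 3.57-fold (3.35 to 3.80) and Sfrp1 3.69-fold (3.26 to 4.17) lower, although Sostdc1 was 1.38-fold higher. Genital patterning genes had a median of −0.23, with Six1 2.27-fold and Fgf10 1.74-fold lower. Extracellular matrix genes had a median of −0.24, which was −0.11 with the trend removed, and Eln was 1.62-fold and Col14a1 1.59-fold lower, although Col3a1 was 1.15-fold higher as deposited. The actomyosin median, at −0.06, reversed to 0.04 with the trend removed. Bmp5 was 2.79-fold and Chrdl1 3.10-fold lower in a BMP and TGF-beta list that did not stand apart (−0.09).

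Steroid genes differed in direction. Ar stood at FPKM 4.78 in the male and 9.13 in the female, 1.91-fold lower (1.75 to 2.09), and Esr1 was 3.52-fold lower (2.36 to 5.20). Srd5a2, whose product makes dihydrotestosterone, was 1.61-fold higher in the male (1.38 to 1.87). Rescaled to equal totals, Ar stood at 6.12 in the male and 13.9 in the female, and Srd5a2 at 27.6 and 20.5. The steroid receptor and enzyme list as a whole did not stand apart (−0.04), and neither did the Maf family, androgen response, Wnt target, smooth muscle, basal epithelium, urothelium, endothelium or neural lists, with medians from −0.13 to 0.14. With the trend removed, basal epithelium (0.18), endothelium (−0.14) and the BMP and TGF-beta list (−0.14) did stand apart. So did the steroid list with libraries rescaled to the same total (−0.34) or with no minimum level (−0.27), and androgen response genes at a minimum FPKM of 5 (0.25).

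**Figure D3:**
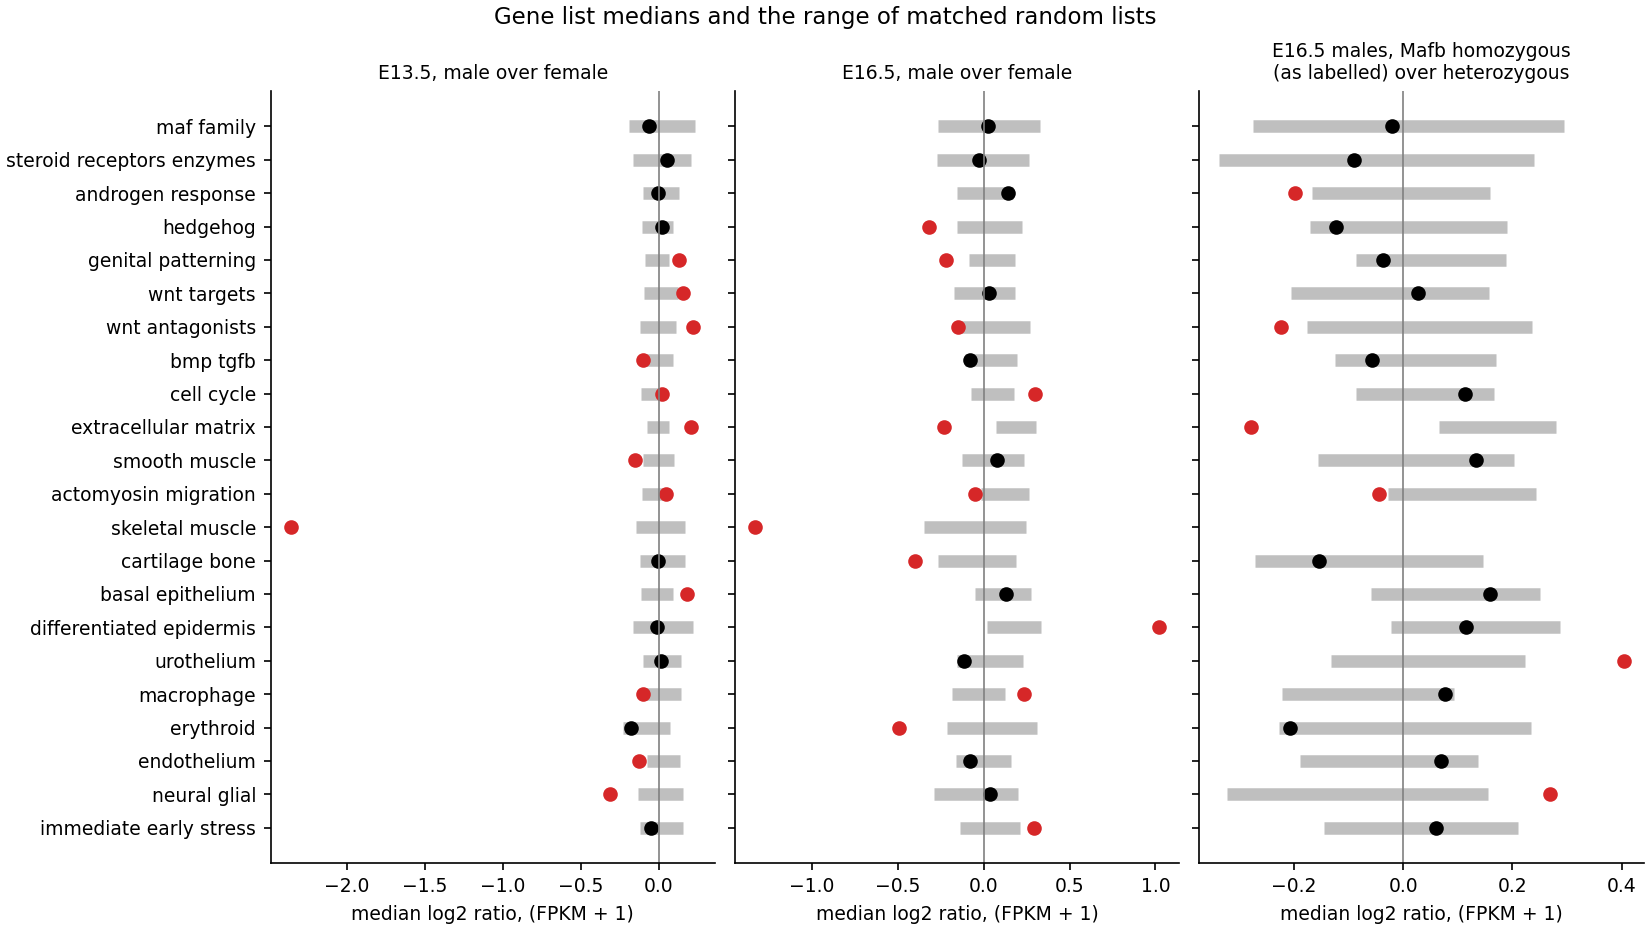
Median log2 ratio of each gene list in the 3 comparisons, without subtracting the median gene, 1 panel each with its own horizontal scale. Red points stood apart from the matched random lists, black points did not, and grey bars span the range of the middle 95% of 10000 random lists. On this scale differentiated epidermis reached 1.02 in the E16.5 sex comparison and urothelium 0.40 in the Mafb comparison.

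The sex differences at the 2 stages overlapped in part. The skeletal muscle genes Acta1, Actc1, Myl1, Mylpf, Myog and Tnnc2 and the liver genes Alb, Afp, Apoa1 and Apoa2 were at least 2-fold lower in the male at both. With sex chromosomes left out, 16 genes were higher and 45 lower in the male at E13.5, and 20 of 11918 genes passed 2-fold in the same direction at both stages, 15 of them lower in the male, against 0.367 from lists that were independent, and 6 in opposite directions against 0.375. The 5 shared male-higher genes were Amd2, Eif3j1, Rps27, Fam25c and Gm3219. Amd2, Eif3j1 and Rps27 have near-identical copies, and Gm3219 is an unnamed predicted gene. Fam25c rested on about 6 fragments against 0 at E13.5. Across genes, which are not independent replicates, the ratios at the 2 stages had a Pearson correlation of −0.11 and a Spearman correlation of −0.33. With the trend on GC content and length removed these were 0.04 and −0.14. Before that, the ratio followed transcript length in opposite directions, with a Spearman correlation of 0.48 at E13.5 and −0.45 at E16.5. Sex chromosome genes added 6 genes in the same direction, including Xist and the Y-linked Ddx3y.

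Between the library labelled homozygous and the library labelled heterozygous for the Mafb allele, few genes differed by 2-fold. Urothelial genes were higher in the library labelled homozygous. Extracellular matrix, Wnt antagonist and androgen response genes were slightly lower there, with Ar and Ptch1 among the lower genes. The comparison asked what depends on Mafb in the male region. Mafb itself did not differ detectably between the libraries as deposited, so each direction below holds for the labels only. Of 13676 genes, 54 were at least 2-fold higher and 66 at least 2-fold lower. Among the 13033 with a known length these were 44 and 58, against 5.85 and 6.25 from counting error alone. Rescaled to equal totals the split was 53 and 154, so the share of higher genes was 45.0% as deposited and 25.6% rescaled. With the trend on GC content and length removed it was 23 higher and 82 lower, a share of 21.9%. The trend was steepest in this comparison, with a Spearman correlation across genes of 0.47 between the ratio and GC content and of −0.57 between the ratio and length. In the sex comparisons the correlation with length was 0.48 at E13.5 and −0.45 at E16.5. Folds of single genes in all comparisons are given without removing the trend.

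Ubc was 3.62-fold (3.30 to 3.98), Cebpb 2.93-fold (2.70 to 3.19) and Mid1 2.85-fold (2.69 to 3.02) higher in the library labelled homozygous. Gast was 10.1-fold higher, from about 10 fragments against 1 (1.38 to 422). Fabp3 was 8.92-fold (2.38 to 41.0) and Dleu2 4.62-fold (2.85 to 7.78) lower. Rps27, Hba-a1, Hbb-b1, Eif3j1 and Rnaset2a also passed 2-fold and have near-identical copies. Where Eif3j1 was lower, its copy Eif3j2 was higher, by 0.85 times as much FPKM. Of the 120 genes past 2-fold, 32.5% shared a locus with another gene, against 17.2% of all genes measured.

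Urothelial genes had a median of 0.42, above all matched random lists, with 12 of 14 genes higher in the library labelled homozygous. Upk2 was 1.78-fold (1.44 to 2.22), Upk1a 1.66-fold (1.42 to 1.93), Krt19 1.53-fold (1.47 to 1.59) and Krt7 1.41-fold (1.38 to 1.45) higher. Neural and glial genes had a median of 0.28, with Nefl 2.71-fold and Sox10 1.53-fold higher, but did not stand apart at a minimum FPKM of 5 or with the trend removed. The extracellular matrix median was −0.26, below all matched random lists, with 22 of 29 genes lower. Thbs2 was 1.56-fold (1.44 to 1.69) and Col12a1 1.49-fold (1.42 to 1.57) lower, while the median was −0.05 with the trend removed. Androgen response genes, a list that includes Mafb, had a median of −0.18, with Zbtb16 1.98-fold (1.72 to 2.29) and Klf9 1.52-fold lower, although Mt2 was 1.80-fold higher. Wnt antagonists had a median of −0.21, with Frzb and Sfrp4 each 1.71-fold lower although Sfrp2 was 1.21-fold higher, and did not stand apart with no minimum level or with the trend removed. The actomyosin median, at −0.03, reversed to 0.01 with the trend removed.

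Ar was 1.63-fold (1.49 to 1.79) and Ptch1 1.72-fold (1.59 to 1.86) lower in the library labelled homozygous. These folds are without removing the trend on length, and their intervals do not cover it. Shh at 1.0 (0.871 to 1.15) and Srd5a2 at 1.01 (0.886 to 1.16) did not differ detectably. Among the Maf family, Mafg was 1.46-fold lower (1.35 to 1.59). The lists of the Maf family, steroid receptors and enzymes, hedgehog, genital patterning, Wnt targets, BMP and TGF-beta, cell cycle, smooth muscle, cartilage and bone, basal epithelium, differentiated epidermis, macrophage, erythroid, endothelium and immediate-early genes did not stand apart, with medians from −0.19 to 0.17. With the trend removed, 5 of them did: cell cycle genes were higher (0.23), and hedgehog (−0.13), cartilage and bone (−0.20), erythroid (−0.33) and immediate-early genes (−0.15) were lower. At a minimum FPKM of 5, macrophage (0.25), endothelium (0.15) and erythroid genes (0.47) stood apart on the high side, so the erythroid direction depends on the processing. Fewer than 5 skeletal muscle genes were measured.

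Genes that differed between the sexes at E16.5 were then read in the Mafb comparison, to ask whether male-higher genes were lower in the library labelled homozygous. The 215 measured male-higher genes, which include Mafb and the Lce genes, had a median of 0.02, at percentile 46.5 of the matched random lists. With the trend removed their median was −0.10, below all of them. The 91 measured female-higher genes, among them Alb and Afp, had a median of −0.21, at percentile 0.025, and −0.16 with the trend removed. Both sets were therefore lower with the trend removed, rather than in opposite directions. With sex chromosomes left out, 15 genes passed 2-fold in the same direction in the sex comparison at E16.5 and the Mafb comparison against 0.956 from independent lists, with Rps27 and Hba-a1 among them, and 6 in opposite directions against 1.08. Across genes the ratios of these comparisons had a Pearson correlation of 0.29 and a Spearman correlation of 0.42, and of 0.18 and 0.28 with the trend removed. The E13.5 sex comparison and the Mafb comparison had a Pearson correlation of −0.23 and a Spearman correlation of −0.45. Their ratios followed transcript length in opposite directions, with Spearman correlations of 0.48 and −0.57. The correlation of this pair was not computed with the trend removed, so an inverse relation cannot be told apart from that trend. These comparisons shared 13 genes past 2-fold in the same direction against 0.186, and 3 in opposite directions against 0.165. Among the 13 were Rps27, Hba-a1, Rnaset2a and Snurf, of near-identical or overlapping families. The small RNAs Scarna13 and Snord17 and the liver genes Alb and Afp were also among them, as were Foxl2, Cox7a1 and Fabp3.

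Between E13.5 and E16.5, epidermal differentiation, extracellular matrix and immediate-early genes were higher and cell cycle genes lower in both sexes. These levels come from separately normalized tables and were rescaled to a common total. Both E13.5 libraries were in the same table and both E16.5 libraries in a different table. Any difference between the tables therefore enters the male and female changes alike. The shared genes and correlations below cannot separate such a difference from stage. Of 14541 genes, 1546 were at least 2-fold higher and 592 at least 2-fold lower at E16.5 in both sexes, against 300.4 and 95.7 from independent lists. Across genes the male and female changes had a Pearson correlation of 0.89 and a Spearman correlation of 0.82. Mafb was higher at E16.5 by a log2 ratio of 4.89 in males and 3.73 in females. Dmkn, Krtdap, Krt13, Stfa3, Cnfn, Krtap13, Fam25c, Ly6d, Krt77 and Crct1 had the highest ratios in both sexes, and Hbb-y, Lix1, Hba-x, Hbb-bh1, Rprm, Lbx2, Fndc3c1, Stra6, Tcf21 and Hmga2 the lowest.

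The median gene changed by −0.25 in males and 0.11 in females, and the medians here are relative to it. Differentiated epidermis genes had a median of 7.96 in males and 7.25 in females, with all 17 at least 2-fold higher in both. Extracellular matrix genes had medians of 1.89 and 2.46, immediate-early genes 2.02 and 1.72, macrophage genes 1.53 and 1.04, basal epithelium genes 1.62 and 1.79 and Maf family genes 1.26 and 1.21, in males and females in that order. Androgen response genes had medians of 1.42 and 0.82, and Wnt antagonists 1.07 and 1.31. Cell cycle genes had medians of −1.35 and −1.62, with 24 of 26 at least 2-fold lower in both sexes. Skeletal muscle genes were −1.59 in females and 0.35 in males, and hedgehog genes −0.53 in males and −0.15 in females, of which 0.35 and −0.15 did not stand apart.

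**Figure D4:**
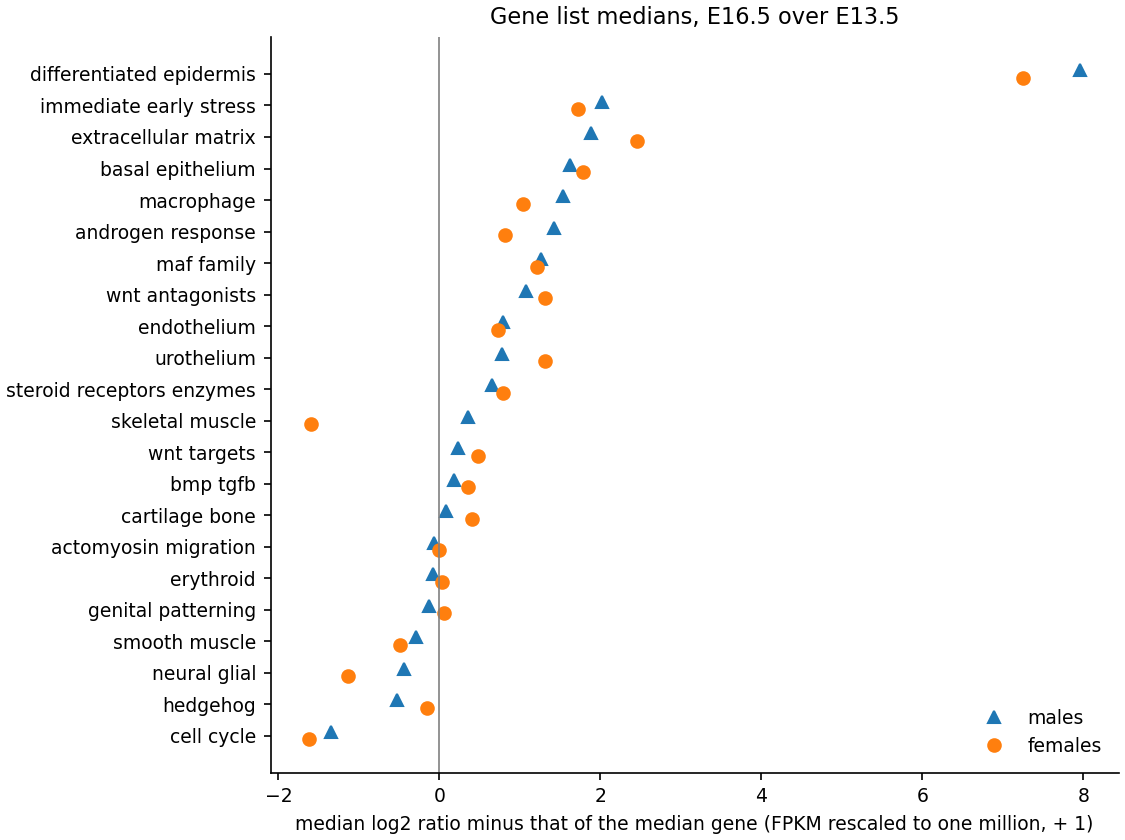
Median log2 ratio of each gene list minus that of the median gene, E16.5 over E13.5, along the horizontal axis, with triangles for males and circles for females, after rescaling each library to a common total. Differentiated epidermis reached 7.96 in males and 7.25 in females, and cell cycle genes were at −1.35 and −1.62.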

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

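None of these differences was tested, since each group has 1 library, and all were picked because the male over female difference went in opposite directions at E13.5 and E16.5; the check against the GC content and length trend was chosen after the results were seen. Values are log2 ratios at E16.5 minus those at E13.5, without subtracting the median gene.

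Genital patterning genes differed by −0.35, Wnt antagonists by −0.37 and extracellular matrix genes by −0.44, each higher in the male at E13.5 and lower at E16.5. With the trend removed these lists kept opposite directions, at 0.09 and −0.22 for genital patterning, 0.16 and −0.18 for Wnt antagonists and 0.14 and −0.11 for extracellular matrix. Actomyosin genes differed by −0.10 and macrophage genes by 0.34, but with the trend removed neither list stood apart at either stage.

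Among single genes past 2-fold in opposite directions, S100a8 differed by 6.15, Gm5483 by 3.30, Adh1 by 2.63 and H2-L by 2.26, each lower in the male at E13.5 and higher at E16.5. Tmsb15a differed by −3.02, Iigp1 by −2.62 and 1700120K04Rik by −2.44, each higher in the male at E13.5 and lower at E16.5. S100a8 was listed at 0 in the E13.5 male. Tmsb15a belongs to a near-identical family and had about 3 fragments in the E13.5 male against 0 in the female. Its fold interval there starts at 0.832 and so includes no change. No explanation was tested for any of these genes.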

How the results depend on the processing

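The cause of a changed value was not tested unless stated. Runs without the ambiguous gene classes and with the GC content and length trend removed were chosen after seeing the data. Counts are genes higher and lower in the male, or in the library labelled homozygous. With a pseudocount of 0.1 they were 61 and 146 at E13.5, 374 and 279 at E16.5 and 140 and 219 in the Mafb comparison. A pseudocount of 5, which shrinks low genes by construction, gave 10 and 18, 117 and 26, and 14 and 11, with 876 genes higher and 310 lower between stages in both sexes. A minimum FPKM of 5, which tests fewer genes, gave 14 and 27 at E13.5, 66 lower at E16.5, and 29 and 31 in the Mafb comparison. Rescaled to 1000000, 43 genes were higher at E13.5, 288 lower at E16.5 and 154 lower in the Mafb comparison. After also leaving out erythroid, muscle and epidermal genes these were 43, 268 and 155. Without ambiguous gene classes, 13 genes were higher at E13.5, and 27 were higher and 38 lower in the Mafb comparison. With the trend removed, 23 were higher there. No minimum level and centring on the median gene kept every count within 1.5 times.

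The 20 genes shared by the sex differences at both stages were 3 with a pseudocount of 5, 6 at a minimum FPKM of 5, 43 at 1.5-fold and 13 without cell type markers. Male-higher genes had a median of 0.01 in the Mafb comparison, before subtracting the median gene, inside the range of random lists, but stood apart on the high side at 0.031 with a pseudocount of 0.1 and at 0.10 at 1.5-fold, and on the low side at 0.012 with a pseudocount of 5 and at −0.10 with the trend removed. Female-higher genes stood apart below 0 in every run.

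Of 13 lists that stood apart at E13.5, 9 did so under every alternative fixed beforehand that gave a value and 8 also with the trend removed; at E16.5 these were 11 and 9 of 12, and in the Mafb comparison 4 and 3 of 6. With the trend removed, 3 medians of these lists reversed: cell cycle at E13.5 to −0.015, actomyosin at E16.5 to 0.035 and actomyosin in the Mafb comparison to 0.013. Lists that stood apart in another run but not in the first numbered 2 at E13.5, 2 at E16.5 and 3 in the Mafb comparison under the alternatives fixed beforehand, and 1, 3 and 5 with the trend removed. In the Mafb comparison immediate-early genes also reversed, to −0.15, and erythroid genes stood apart on opposite sides, at 0.47 with a minimum FPKM of 5 and −0.33 with the trend removed. At E13.5, smooth muscle no longer stood apart with no minimum level, macrophage genes with a pseudocount of 5 or no minimum level, BMP and TGF-beta genes with a pseudocount of 5 or a minimum FPKM of 5, and actomyosin genes in both rescaled runs. The erythroid list at E16.5 was lost at a minimum FPKM of 5, and in the Mafb comparison neural genes at a minimum FPKM of 5 and Wnt antagonists with no minimum level. No named gene past 2-fold changed direction in any run. Counting only genes with separate intervals was not run, since the files give none. No paired analysis was run, and leaving out a replicate was impossible because each group has 1 library.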

Other observations

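The test of the extracellular matrix list against GC content and length was fixed before its result was seen; the other tests here were chosen, or changed, after results were seen. Every pattern was found and tested on the same libraries and remains a hypothesis. Medians and bounds here are given without subtracting the median gene.

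Several genes past 2-fold belong to near-identical or overlapping families, and reads shared between copies may account for some of them. In 9 of 22 cases in which a member passed 2-fold, the rest of its family moved the other way by 0.5 to 1.5 times the member's change in FPKM, against a mean of 1.80 with random genes at the level of the rest. In the other cases it did not, so shared reads as the cause of most of them could not be decided. A first test on summed FPKM was dropped, since the member alone could have moved the sum 2-fold in only 3 cases. For the adult globins, splitting reads between copies is argued against on the deposited values only. The test asked that the log2 ratios of the alpha and beta sums both be 1 or more. As deposited, the smaller was 1.24 in favour of the male. With libraries rescaled to the same total, the alpha ratio fell just below that limit. What differs in the adult globins was not tested, and more blood in 1 sample stays open. The embryonic globins went the other way, at a summed FPKM of 17.3 in the male and 42.3 in the female.

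Late epidermal genes were far higher in the E16.5 male. Sharing of reads between paralogs is argued against, as the sum over all 21 late cornified envelope genes was 9.52-fold higher. A larger share of all epithelium is argued against too, for this pair of libraries only. The basal epithelium median was 0.13, or 0.18 and apart from the random lists with the trend removed. Its upper bootstrap bound, over the genes of the list, was 0.32, below the lower bound of 0.66 for differentiated epidermis. Whether the male sample was further along the change from E13.5 to E16.5 could not be decided. The gene sets used compared the Mafb table's C57BL/6 libraries at E16.5 with the ICR libraries at E13.5. Strain, genotype label and table therefore differed along with stage. Genes higher at E16.5 had a median of 0.19, or 0.14 with the trend removed, above all random lists as that explanation expects. Genes lower at E16.5 had a median of 0.030 with the trend removed, also above the random lists, but lay inside their range without that correction. Fixed lists, whose stage changes include the E16.5 libraries of the sex comparison, went both ways. Immediate-early genes, which rose with stage, were higher in the male (0.29). Against that explanation, cell cycle genes, which fell, were higher (0.30, or 0.32 with the trend removed). Extracellular matrix genes, which rose, were lower (−0.23, or −0.11), also against it. A first version with sets chosen on the same E16.5 libraries had the higher set at 0.26 but the lower set at 0.14, against that explanation, and was replaced after it was seen, since the sets shared libraries with the comparison; a true sex difference and a dissection with more cornified skin stay open, and neither was tested.

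The extracellular matrix list was lower in the library labelled homozygous, although Mafb itself, as deposited, was not. The GC content and length trend may explain much of it: with the trend removed the median was −0.052, with bootstrap bounds of −0.11 and 0.01, still at percentile 1.47 of the random lists, so the trend as the whole cause could not be decided. A lower share of mesenchyme could not be decided either, since the lowest upper bound among the other cell types, 0.28 for endothelium, was above the highest lower bound, 0.24 for urothelium. That explanation needs every other cell type above 0, and the erythroid median was −0.21, against it, although its bounds of −0.54 and 0.70 span 0. That test left out cartilage and bone, itself mesenchymal, after its upper bound of −0.02 had been seen to lie apart from urothelium. The genotype, the embryos and the preparation differ together with the label, and none of these was tested alone.

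Genes of secreted liver proteins were lower in the male at both stages. Their summed FPKM was 2.67 in the male and 16.8 in the female at E13.5, 13 and 143 at E16.5, and 76.6 and 37.6 in the libraries labelled heterozygous and homozygous. Skeletal muscle genes summed to 9.19 in the male and 126 in the female at E13.5, 11.7 and 34.0 at E16.5, and 12.5 and 14.3 in the libraries labelled heterozygous and homozygous. The source of these transcripts was not tested.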
